A study of Mus musculus with 18 samples.

How the data were processed

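The 18 arrays were taken from the deposited tables, whose values per the labels are signal intensities on a linear scale. They ran from 0.4 to 441059.8, and the mean of each array without the outer 2% on either side was about 2501, so the arrays were scaled to a common mean before they were deposited. The software that made the values is not given in the sources used here, and no detection calls were used here. Array medians ran from 793.4 to 935.7, a ratio of 1.18, under the limit of 1.25 set before the data were examined, so the values were used as deposited. Values under the floor of 143.5, the 20th percentile of all values, were set to the floor, and log2 was taken.

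The array held 12488 probes. The 66 control probes were left out of the tests, 10855 probes had 1 gene symbol, 396 had several and 1237 had none. Gene symbols were taken from the array annotation, and 0 were changed when checked through Entrez identifiers. Probes were tested if the highest of the 8 group means was at least the median of all log2 values (9.73), which left 7134 probes for 5438 genes.

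The culture and treatment details were taken from the labels. They state that mRNA was pooled from 6 cultures per array, collected 72 h after the last serum and 24 h after confluence. The doses in the mix were 1 µM BRL49653, 1 µM dexamethasone, 0.5 µM IBMX and 10 µg/mL insulin. The letters UT are not spelled out in the labels, and were read as the group without EGF, TCDD or IDMB. Separate arrays were treated as replicates as labelled.

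Fold changes were estimated with limma 3.58.1 in R 4.3.3, with 1 mean per group fitted over all 18 arrays. The variance was moderated with a trend on the mean (residual degrees of freedom 10, prior 6.03), and p values were adjusted by the Benjamini-Hochberg method over the 7134 probes within each comparison. Probes with adjusted p under 0.05 are called higher or lower. The 8 groups share 1 estimate of spread, which is needed because 6 of them hold 2 arrays, and the number of arrays limits the precision. Mean effects weight the 4 backgrounds equally, and interactions are differences between them. No group holds enough arrays for a test of single outlying arrays. Every p beside a fold change is from limma unless it is called exact.

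Gene lists were written before the data were examined. They hold 691 genes in 24 lists, of which 582 were on the array and 417 passed the filter. The lists cover AhR targets, adipogenic transcription factors, adipocyte and PPARG target genes, adipogenesis inhibitors, fatty acid synthesis, fatty acid oxidation, cholesterol synthesis, glucocorticoid responsive, cAMP responsive, EGF and MAPK responsive, S phase, G2 and mitosis, extracellular matrix, NRF2, ER stress, interferon, inflammatory and insulin axis genes. Lists for bone and cartilage, skeletal muscle, smooth muscle, macrophage, endothelial and epithelial genes served as markers of other cell types. Endothelial and epithelial genes had fewer than 5 members measured and were not tested. The other 22 lists were tested with camera from limma (preset correlation 0.01, 1 probe per gene) and again with a correlation estimated for each list, with adjustment over the lists within each comparison. Of 352 list tests camera called 94 and the estimated correlation 26, with 68 of the camera calls lost, while fry called 79 for direction and 225 for mixed changes. List scores per array were also compared exactly, by all 3600 relabellings within backgrounds for TCDD and for EGF and all 4320 for IDMB.

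Genes were named by a rule fixed before the data were examined. It admits anchor genes of the lists, each by its probe with the highest signal, and the genes with the largest changes past the threshold in each comparison (up to 8 or 4 in each direction, without overlap of the arrays compared and with at most 1 group wholly at the floor). After the values were seen, the choice among these was narrowed mainly to genes whose calls held when any array was left out, so the printed genes are steadier than those not printed. Members of lists are also named without values where they passed the threshold, whether or not the rule admits them. Where leaving out 1 array moved a fold by over 1.5 times, for 20 pairs of gene and comparison, the leave-one-out range stands beside it. Of the 166 printed pairs, 157 were called and 130 of these were called in every fit with 1 array left out.

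The procedure was tested on 7134 simulated genes, 100 changed by log2 1 and 100 by log2 2. For IDMB against UT it recovered 56% and 93% (15 false of 164 calls), for TCDD against UT 53% and 87% (7 false of 147). For EGF+TCDD against EGF (2 arrays each) it recovered 35% and 87% (5 false of 127). The mean TCDD effect recovered 80% and 99% (9 false of 188), and the EGF by TCDD interaction without IDMB 21% and 71% (3 false of 95). Of 20 simulated lists of independent genes, 4 of 4 shifted by log2 0.4 were called and 0 of 16 others. This left the preset correlation untested.

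Arrays were checked for copies and mixed labels. The correlation of 12 pairs within a group ran from 0.922 to 0.96 (median 0.947), with at most 0.05% identical values, and that of 141 other pairs from 0.814 to 0.956 (median 0.888). The ratios of the 3' to the 5' control probe of Gapdh and of actin were computed for each array. A fit with the log2 Gapdh ratio as a covariate, 1 with the actin ratio for the effects of IDMB alone and 1 with 1 probe per gene were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.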

Results

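C3H10T1/2 mouse fibroblasts were grown with or without an adipogenic mix (IDMB), EGF and TCDD, in all 8 combinations, and their mRNA was read on 18 arrays. IDMB held insulin, dexamethasone, IBMX and BRL49653 (rosiglitazone, a PPARG agonist) and was given for 24 h. EGF was given at 10 nM for 24 h and TCDD, an agonist of the aryl hydrocarbon receptor (AhR), at 10 nM for 72 h. Each array carried mRNA pooled from 6 cultures, and replicates were taken as labelled. The groups named UT, which received none of the 3 treatments, and IDMB had 3 arrays each, and the other groups had 2.

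IDMB for 24 h raised genes of fat cells and of glucocorticoid signalling and lowered interferon and contractile genes (n = 3 against 3). Rgs2, a regulator of G protein signalling, was 26.7-fold higher than in UT (log2 4.74, SE 0.318, limma adjusted p = 4.88e-08). Fkbp5, a glucocorticoid-induced co-chaperone, was 19.6-fold higher (SE 0.296, adjusted p = 6.92e-08). Ctla2b was 41.6-fold higher (SE 0.451, adjusted p = 5.93e-07), the largest rise of a gene. Abhd5, the activator of the fat cell triglyceride lipase, rose 11.3-fold (SE 0.227, adjusted p = 3.34e-08), and Ephx2, soluble epoxide hydrolase, 21.0-fold (SE 0.444, adjusted p = 4.81e-06). Igfbp3, which binds insulin-like growth factors, was at the floor on all UT arrays and rose at least 17.1-fold (SE 0.475, adjusted p = 2.07e-05). Bmp4, a growth factor of bone and fat lineages, dropped by 10.8-fold (log2 -3.43, SE 0.244, adjusted p = 1.03e-07), and the monocyte chemokine Ccl2 by 12.3-fold (SE 0.464, adjusted p = 4.98e-05, leave-one-out 9.23 to 19.3). Ifit1, an interferon-induced gene, was at the floor on all IDMB arrays and at least 14.6-fold lower (SE 0.457, adjusted p = 2.31e-05). The matrix-associated gene Ccn3 was 23.5-fold lower (SE 0.752, adjusted p = 0.000512, leave-one-out 13.1 to 53.8), and the neuropeptide Y receptor Npy1r 14.6-fold lower (SE 0.571, adjusted p = 0.000176, leave-one-out 10.8 to 23.5).

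**Figure D1:**
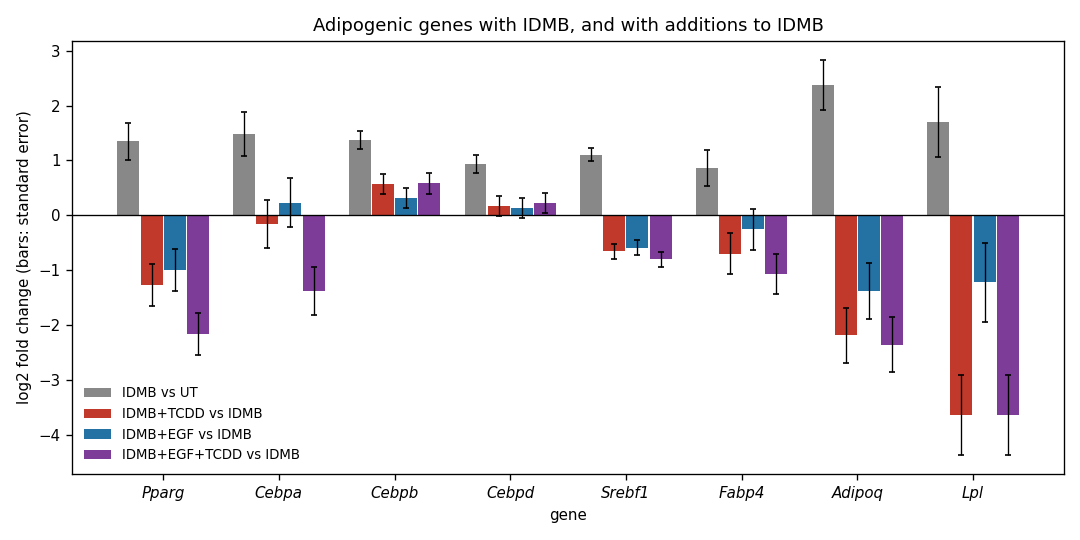
Log2 fold changes of 8 adipogenic genes (limma, with SE): IDMB vs UT, and IDMB with TCDD, EGF or both vs IDMB. Chance on the shared IDMB arrays can give opposite signs.

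Of 15 adipogenic transcription factors measured, 9 rose with IDMB, 1 (Klf4) fell and 5 were not called (10 and 1 when adjusted over the list alone). Cebpb, an early regulator of adipogenesis, rose by log2 1.38 (SE 0.164, adjusted p = 2.57e-05), Cebpd by 0.93 (SE 0.163, adjusted p = 0.000851) and Srebf1, a regulator of lipid synthesis, by 1.11 (SE 0.125, adjusted p = 1.59e-05). Pparg, the main regulator of fat cell differentiation, rose 2.54-fold (SE 0.342, adjusted p = 0.0132), a call lost without UT 3 (0.0637) or without IDMB 1 (0.0646). Cebpa rose by 1.48 (SE 0.396, adjusted p = 0.0183), and its call was lost without UT 1 (0.0789), IDMB 2 (0.0697) or IDMB 3 (0.0901). As a list they were higher (camera adjusted p = 1.48e-05, and adjusted p = 0.00622 with an estimated correlation). Of 22 adipocyte and PPARG target genes, 12 rose and Cav1 fell, with 9 not called (14 and 1 when adjusted over the list alone). That list rose (median log2 1.82, camera adjusted p = 4.14e-08, and adjusted p = 0.00932 with an estimated correlation). Adipoq, the gene of the fat cell hormone adiponectin, rose 5.18-fold (log2 2.37, SE 0.452, adjusted p = 0.00173), beside Plin2, Pnpla2 and Lipe. Fabp4 (0.86, adjusted p = 0.0978) and Lpl (1.70, adjusted p = 0.0965, leave-one-out 0.73 to 2.32) did not pass the test, though Lpl did without UT 3 (0.0323). The probe of Angptl4 with the highest signal rose by log2 2.23 (leave-one-out 1.54 to 2.58), while its other probes gave 1.80 (adjusted p = 0.0698) and -0.86 (adjusted p = 0.285).

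Glucocorticoid responsive genes rose with IDMB, with 19 of 27 higher, Fgf7 lower and 7 not called (19 and 1 when adjusted over the list alone). The list had a median log2 of 1.78 (camera adjusted p = 8.26e-13, and adjusted p = 0.00622 with an estimated correlation). The metallothionein Mt1 rose 6.29-fold (leave-one-out 4.17 to 9.36), the kinase Sgk1 6.54-fold and the clock gene Per1 2.42-fold. Of 8 cAMP responsive genes 3 rose (Id1, Rgs2 and Per1) and Bdnf fell, with 6 and 1 when adjusted over the list alone (median 0.87, camera adjusted p = 0.0125, and adjusted p = 0.0881 with an estimated correlation). Fatty acid synthesis genes were not called as a list (3 higher and 1 lower of 12, camera adjusted p = 0.221), although Scd1, the stearoyl-CoA desaturase, rose 6.87-fold (SE 0.365, adjusted p = 6.18e-05). Irs2, a docking protein of the insulin receptor, rose 5.17-fold (SE 0.495, adjusted p = 0.0035), within an insulin and IGF axis list that was not called (3 higher and 1 lower of 20, camera adjusted p = 0.472).

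Interferon and antiviral genes fell with IDMB, 8 of 19 lower and none higher (11 lower when adjusted over the list alone), with a list median of -0.80 (camera adjusted p = 4.39e-08, and adjusted p = 0.00797 with an estimated correlation). Isg15, a ubiquitin-like interferon product, dropped by 6.66-fold (SE 0.412, adjusted p = 0.000216). Of 15 smooth muscle and contractile genes 9 fell and none rose (11 lower and 1 higher when adjusted over the list alone, median -0.74, camera adjusted p = 4.09e-06, and adjusted p = 0.00932 with an estimated correlation). Acta2, smooth muscle actin, dropped by 6.74-fold (SE 0.174, adjusted p = 3.04e-08) and Tagln by 4.40-fold (SE 0.5, adjusted p = 0.00773). Bone and cartilage genes were 1 higher and 6 lower of 9, the same when adjusted over the list alone (median -1.91, camera adjusted p = 0.00306, and adjusted p = 0.0881 with an estimated correlation). Extracellular matrix genes were split, 13 of 38 lower and 6 higher. Col1a1 fell (log2 -0.85, SE 0.156, adjusted p = 0.0012), and the higher ones included the basement membrane collagens Col4a1 and Col4a2. That list counted 17 lower and 6 higher when adjusted over the list alone (median -0.31, camera adjusted p = 0.00177, and adjusted p = 0.104 with an estimated correlation).

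Cholesterol synthesis genes were 4 lower and none higher of 12 with IDMB (5 lower when adjusted over the list alone, median -0.76, camera adjusted p = 0.0115, and adjusted p = 0.324 with an estimated correlation). Adipogenesis inhibitors and preadipocyte genes were 4 lower and 1 higher of 23 (7 and 2 when adjusted over the list alone, median -0.33, camera adjusted p = 0.0258, and adjusted p = 0.324 with an estimated correlation). Genes of ER stress and the unfolded protein response were 5 lower, among them Hspa5, and 1 higher of 25 (6 and 2 when adjusted over the list alone, median -0.25, camera adjusted p = 0.0265, and adjusted p = 0.324 with an estimated correlation). Camera did not call AhR targets (adjusted p = 0.552), EGF and MAPK responsive genes (0.311), S phase and DNA replication (0.165) or G2 and mitosis genes (0.421). Nor did it call NRF2 and oxidative stress genes (0.946), inflammatory and chemokine genes (0.0879), fatty acid oxidation and mitochondria (0.181), skeletal muscle genes (0.78) or macrophage genes (0.327). In all, IDMB against UT had 475 probes higher and 529 lower of 7134 tested (limma, Benjamini-Hochberg adjusted p under 0.05). These belonged to 405 and 458 genes, and leaving out any 1 array left between 788 and 1050 calls. After scaling to the same median 459 probes were higher and 431 lower. The ratio of the 3' to the 5' actin control probe was 1.37 to 1.43 on the UT arrays and 1.80 to 2.25 on the IDMB arrays. With its log2 as a covariate 482 probes were called, with standard errors 1.4-fold larger, and Pparg (adjusted p = 0.11), Cebpa (0.101) and Adipoq (0.116) lost their calls.

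TCDD for 72 h, against UT, raised classic targets of the AhR and lowered Ccl9, Wfdc21 and Saa3 (n = 2 against 3). Tiparp, a feedback regulator of the AhR, rose 14.7-fold (log2 3.88, SE 0.326, adjusted p = 1.64e-05), the aldehyde dehydrogenase Aldh3a1 10.5-fold (SE 0.33, adjusted p = 6.83e-05) and the quinone reductase Nqo1 3.99-fold (SE 0.229, adjusted p = 0.00021). Fosl1, an AP-1 transcription factor, rose 7.21-fold (SE 0.403, adjusted p = 0.000943, leave-one-out 4.69 to 11.1) and Adh7, an alcohol dehydrogenase active on retinol, 4.97-fold (SE 0.307, adjusted p = 0.000715). The chemokine Ccl9 dropped by 14.5-fold (SE 0.43, adjusted p = 0.000182), Wfdc21 by 11.3-fold (SE 0.571, adjusted p = 0.00314, leave-one-out 7.54 to 16.4) and the acute phase gene Saa3 by 7.70-fold (SE 0.402, adjusted p = 0.000715). Of 12 AhR targets 7 rose and Ahr itself fell (8 and 1 when adjusted over the list alone), with a list median of 0.96 (camera adjusted p = 1.91e-05, and adjusted p = 0.0495 with an estimated correlation). Cyp1b1 rose by 0.97 (SE 0.185, adjusted p = 0.00681), a call lost without TCDD 1 (0.0944). Cyp1a1, the best known AhR target, rose by 2.21 (SE 0.6, adjusted p = 0.035, leave-one-out 1.24 to 3.17), lost without UT 1 (0.0902), UT 2 (0.0798) or TCDD 1 (0.392). Chil1 was higher by 3.21 (adjusted p = 0.00547), lost without TCDD 2 (0.0664).

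Cell cycle lists were higher with TCDD against UT by camera, yet with few single calls. S phase and DNA replication genes had 4 of 30 higher (14 when adjusted over the list alone, median 0.83, camera adjusted p = 2.92e-06, and adjusted p = 0.517 with an estimated correlation), among them Mcm5 and Mcm7 of the replicative helicase. G2 and mitosis genes had 2 of 33 higher, also 2 when adjusted over the list alone (median 0.95, camera adjusted p = 2.92e-06, and adjusted p = 0.691 with an estimated correlation). Its list score was 1.74 on TCDD 1 and 0.24 on TCDD 2. The adipocyte list was lower by camera (median -0.40, adjusted p = 0.0201, and adjusted p = 0.455 with an estimated correlation), with only Fabp4 called, and none when adjusted over the list alone. Smooth muscle and contractile genes had 4 lower, among them Acta2 (log2 -1.03, SE 0.195, adjusted p = 0.00626, lost without TCDD 1 at 0.0713), and 1 higher of 15 (8 and 2 when adjusted over the list alone, median -0.55, camera adjusted p = 0.0201, and adjusted p = 0.455 with an estimated correlation). Extracellular matrix genes had 3 lower and 1 higher of 38 (8 and 1 when adjusted over the list alone, median -0.25, camera adjusted p = 0.0181, and adjusted p = 0.455 with an estimated correlation). Both of these calls were lost after quantile normalization (0.508 for smooth muscle and 0.669 for matrix). Fatty acid oxidation and mitochondria genes had 4 lower and none higher of 31, the same when adjusted over the list alone (median -0.16, camera adjusted p = 0.0181, and adjusted p = 0.455 with an estimated correlation). Interferon genes (1 higher of 19, camera adjusted p = 0.149) and inflammatory and chemokine genes (2 higher and 3 lower of 19, camera adjusted p = 0.144) were not called.

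TCDD against UT had 277 probes higher and 271 lower. Scaling each array to the same median gave 175 higher and 308 lower. The brightest values were lower on the TCDD arrays, where 0.1% of probes exceeded 115493 and 77274, against 139730 to 170579 on the UT arrays, and quantile normalization gave 262 higher and 271 lower. The count was 178 without UT 2, 136 without TCDD 1 and 114 without TCDD 2, and where a group was left with 1 array, that array was assumed to vary like the other groups. The ratio of the 3' to the 5' Gapdh control probe was 0.854 and 0.919 on the TCDD arrays and at most 1.52 on the UT arrays, all above those with TCDD. With its log2 as a covariate 36 probes were called.

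EGF for 24 h, against UT, raised Fosl1, Dusp6 and 26 of 33 G2 and mitosis genes (n = 2 against 3). Fosl1 rose 10.8-fold (log2 3.44, SE 0.403, adjusted p = 0.000568) and Dusp6, a phosphatase that restrains ERK, 10.7-fold (SE 0.523, adjusted p = 0.00398), the latter lost without EGF 2 (0.0634). Saa3 was at the floor on the EGF arrays and at least 43.8-fold lower (SE 0.402, adjusted p = 2.41e-06), and Npy1r was 23.2-fold lower (SE 0.639, adjusted p = 0.00355, leave-one-out 17.2 to 37.3). The contractile gene Tagln dropped by 10.3-fold (SE 0.559, adjusted p = 0.00488) and the haptoglobin gene Hp by 5.68-fold (SE 0.416, adjusted p = 0.00488), both lost without EGF 2 (0.0935 and 0.0967). Of 33 G2 and mitosis genes 26 rose and none fell (32 higher when adjusted over the list alone), with a median of 1.98 (camera adjusted p = 1.4e-20, and adjusted p = 0.244 with an estimated correlation). The proliferation marker Mki67 rose 6.22-fold (SE 0.644, adjusted p = 0.0256), the mitotic kinase Cdk1 4.43-fold (SE 0.46, adjusted p = 0.0144) and the topoisomerase Top2a by log2 2.32 (SE 0.525, adjusted p = 0.0196). Without UT 2, EGF 1 or EGF 2 their calls were lost (adjusted p of 0.11, 0.112 and 0.195 for Mki67, 0.0762, 0.077 and 0.148 for Cdk1, and 0.0916, 0.107 and 0.147 for Top2a). S phase and DNA replication genes had 17 of 30 higher and none lower (23 higher when adjusted over the list alone, median 1.32, camera adjusted p = 3.24e-15, and adjusted p = 0.244 with an estimated correlation).

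EGF and MAPK responsive genes had 7 of 30 higher with EGF, among them Egr1, Egr2 and Errfi1, and Cxcl1 lower (11 and 2 when adjusted over the list alone, median 0.34, camera adjusted p = 0.009, and adjusted p = 0.365 with an estimated correlation). Inflammatory and chemokine genes had 6 of 19 lower, among them Cxcl12 and Lcn2, and Cx3cl1 higher (7 and 1 when adjusted over the list alone, median -0.14, camera adjusted p = 0.00616, and adjusted p = 0.244 with an estimated correlation). The adipocyte list had 3 of 22 lower (Hp, Fabp4 and Plin4; 5 when adjusted over the list alone, median -0.40, camera adjusted p = 0.0149, and adjusted p = 0.244 with an estimated correlation). Smooth muscle and contractile genes had 5 of 15 lower (7 lower and 2 higher when adjusted over the list alone, median -0.20, camera adjusted p = 0.0403, and adjusted p = 0.244 with an estimated correlation). Interferon genes had 2 of 19 lower (4 when adjusted over the list alone, median -0.35, camera adjusted p = 0.0267, and adjusted p = 0.244 with an estimated correlation). Cholesterol synthesis genes were higher as a list with no member called (median 0.57, camera adjusted p = 0.024, and adjusted p = 0.365 with an estimated correlation). EGF against UT had 256 probes higher and 184 lower. The count was 105 without UT 2, 114 without EGF 1 and 14 without EGF 2. The Gapdh ratio was 1.43 and 2.47 on the EGF arrays, and 189 probes were called with it as a covariate.

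EGF and TCDD together, against UT, raised AhR targets and 13 of 33 G2 and mitosis genes (n = 2 against 3). Aldh3a1 rose 23.0-fold (log2 4.52, SE 0.33, adjusted p = 2.08e-06), Tiparp 15.0-fold (SE 0.326, adjusted p = 7.32e-06). Nqo1 rose 5.04-fold (SE 0.229, adjusted p = 3.74e-05) and Cyp1b1 2.76-fold (SE 0.185, adjusted p = 0.000453). Cyp1a1 rose 13.7-fold (SE 0.6, adjusted p = 0.00219), lost without EGF+TCDD 1 (0.0632). Chil1, a secreted chitinase-like protein, was higher by log2 4.09 (SE 0.572, adjusted p = 0.000977). The natriuretic peptide clearance receptor Npr3 dropped by 11.9-fold (SE 0.481, adjusted p = 0.000856), Npy1r by 16.6-fold (SE 0.639, adjusted p = 0.00219, leave-one-out 12.3 to 26.7) and Ccl9 by 11.5-fold (SE 0.43, adjusted p = 0.00032). Lox, which crosslinks collagen, was lower by log2 -1.31 (SE 0.199, adjusted p = 0.00193), while its other probe was not called (-0.82, adjusted p = 0.495). Dusp6 was higher by 3.22 (adjusted p = 0.00246), lost without EGF+TCDD 1 (0.0546).

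AhR targets had 6 of 12 higher and none lower with both agents, the same when adjusted over the list alone (median 1.01, camera adjusted p = 1.01e-07, and adjusted p = 0.0134 with an estimated correlation). G2 and mitosis genes had 13 of 33 higher (32 when adjusted over the list alone, median 1.73, camera adjusted p = 1.15e-15, and adjusted p = 0.303 with an estimated correlation). S phase genes had 15 of 30 higher (23 when adjusted over the list alone, median 1.15, camera adjusted p = 1.04e-14, and adjusted p = 0.175 with an estimated correlation). EGF and MAPK responsive genes had 10 of 30 higher, the same when adjusted over the list alone (median 0.52, camera adjusted p = 2.28e-05, and adjusted p = 0.197 with an estimated correlation). The adipocyte list had 3 of 22 lower (Hp, Ech1 and Plin4), the same when adjusted over the list alone (median -0.50, camera adjusted p = 0.0001, and adjusted p = 0.109 with an estimated correlation). Smooth muscle genes had 4 lower and 1 higher of 15 (6 and 1 when adjusted over the list alone, median -0.56, camera adjusted p = 0.002, and adjusted p = 0.109 with an estimated correlation). The comparison had 211 probes higher and 174 lower, or 133 higher and 179 lower after scaling to the same median. The count was 112 without UT 2, 46 without EGF+TCDD 1 and 79 without EGF+TCDD 2. The Gapdh ratio was 2.34 and 2.71 on the EGF+TCDD arrays, and 10 probes were called with it as a covariate.

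TCDD added to IDMB lowered fat cell genes and raised interferon genes, Aldh3a1 and Nqo1 against IDMB alone (n = 2 against 3). Plin4, a coat protein of lipid droplets, dropped by 16.6-fold (log2 -4.05, SE 0.61, adjusted p = 0.000895, leave-one-out 10.7 to 25.8). Adipoq dropped by 4.56-fold (SE 0.506, adjusted p = 0.0159), a call lost without IDMB 2 (0.0532), IDMB+TCDD 1 (0.0758) or IDMB+TCDD 2 (0.118). Lpl, lipoprotein lipase, was at the floor with TCDD and at least 12.4-fold lower (SE 0.721, adjusted p = 0.00585), lost without IDMB+TCDD 2 (0.0567). Its other probe gave -2.24 (adjusted p = 0.0798). Of the 22 adipocyte and PPARG target genes 7 fell and none rose (11 lower when adjusted over the list alone), with a median of -0.90 (camera adjusted p = 1.81e-08, and adjusted p = 0.0355 with an estimated correlation). Among transcription factors, Srebf1 was lower by log2 -0.66 (SE 0.14, adjusted p = 0.00959), lost without IDMB+TCDD 2 (0.155). Pparg stood at -1.27 and did not pass (SE 0.383, adjusted p = 0.0584), although it did without UT 3 (0.0497), IDMB+EGF+TCDD 1 (0.0473) or IDMB+EGF+TCDD 2 (0.0456). Cebpa (-0.15, adjusted p = 0.884) and Fabp4 (-0.70, adjusted p = 0.282) were not called. Acta2 dropped by 3.43-fold (SE 0.195, adjusted p = 0.000129), Ccl9 by 30.1-fold (SE 0.43, adjusted p = 9.7e-06) and Ctla2b by 12.2-fold (SE 0.505, adjusted p = 0.00054).

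Aldh3a1 rose 20.6-fold with TCDD in IDMB cultures (SE 0.33, adjusted p = 2.22e-06), Nqo1 3.31-fold (SE 0.229, adjusted p = 0.000375) and Cyp1b1 2.35-fold (SE 0.185, adjusted p = 0.000895), while Cyp1a1 was not called (log2 0.75, adjusted p = 0.503). AhR targets had 5 higher and Ugdh lower of 12 (6 and 2 when adjusted over the list alone, median 0.66, camera adjusted p = 0.0265, and adjusted p = 0.192 with an estimated correlation). The interferon-induced GTPase Iigp1 rose 7.69-fold (SE 0.416, adjusted p = 0.00054). With Ifi47 and the immunoproteasome subunit Psmb9 it made 3 of 19 interferon genes higher (6 when adjusted over the list alone, median 0.43, camera adjusted p = 7.09e-05, and adjusted p = 0.046 with an estimated correlation). Bone and cartilage genes had 2 of 9 higher, Ogn and the osteoclast inhibitor Tnfrsf11b, and all 9 when adjusted over the list alone (median 0.88, camera adjusted p = 4.3e-05, and adjusted p = 0.046 with an estimated correlation). The chemokine Cxcl12 rose 2.78-fold (SE 0.209, adjusted p = 0.00054) and the membrane protein Tmem176a 7.68-fold (SE 0.487, adjusted p = 0.00177, leave-one-out 5.70 to 12.3). Glucocorticoid responsive genes were not called as a list (3 higher and 1 lower of 27, camera adjusted p = 0.984). The comparison had 218 probes higher and 252 lower, or 200 higher and 181 lower after scaling to the same median, with 277 calls without IDMB 2, 195 without IDMB+TCDD 1 and 151 without IDMB+TCDD 2. The Gapdh ratio was 1.05 and 1.09 on the IDMB+TCDD arrays and 1.19 to 1.73 on the IDMB arrays, and 267 probes were called with it as a covariate.

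EGF added to IDMB raised Egr1 and lowered Saa3 and Acta2 (n = 2 against 3). Saa3 dropped by 12.7-fold (log2 -3.67, SE 0.402, adjusted p = 0.000113) and Acta2 by 3.58-fold (SE 0.195, adjusted p = 9.28e-05). The immediate early factor Egr1 rose 9.54-fold (SE 0.638, adjusted p = 0.00973), lost without IDMB+EGF 1 (0.0777) or 2 (0.0573). The calcium channel subunit Cacna1g rose 11.5-fold (SE 0.591, adjusted p = 0.00396, leave-one-out 7.79 to 18), the ERK-binding protein Pea15a 8.44-fold (SE 0.508, adjusted p = 0.00369). Gpr137b dropped by 10.6-fold (SE 0.601, adjusted p = 0.00559, leave-one-out 8.27 to 16.4). The calls of these 3 genes were lost without IDMB+EGF 1 (0.0663, 0.0701 and 0.0518). Of the 22 adipocyte genes 4 fell (Plin2, Hp, Pnpla2 and Ephx2) and none rose, the same when adjusted over the list alone (median -0.53, camera adjusted p = 0.000131, and adjusted p = 0.135 with an estimated correlation). Smooth muscle and contractile genes were not called as a list (1 higher and 2 lower of 15, camera adjusted p = 0.482). Pparg (adjusted p = 0.161) and Adipoq (-1.38, adjusted p = 0.143) were not called.

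Mitosis genes were higher with EGF in IDMB cultures as a list with no member called in either adjustment (G2 and mitosis, median 0.84, camera adjusted p = 3.34e-05, and adjusted p = 0.819 with an estimated correlation). So were S phase genes (median 0.38, camera adjusted p = 0.0377, and adjusted p = 0.819 with an estimated correlation). Bone and cartilage genes had 2 of 9 higher (Col11a1 and Msx1; 5 when adjusted over the list alone, median 0.87, camera adjusted p = 0.000304, and adjusted p = 0.135 with an estimated correlation). The comparison had 137 probes higher and 134 lower, or 82 higher and 109 lower after scaling to the same median, with 119 calls without IDMB 2 and 30 without IDMB+EGF 1. The Gapdh ratio was 1.75 and 1.76 on the IDMB+EGF arrays.

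EGF and TCDD added together to IDMB lowered fat cell genes and raised AhR targets against IDMB alone (n = 2 against 3). Plin4 was at the floor and at least 25.8-fold lower (log2 -4.69, SE 0.61, adjusted p = 0.000217), Ephx2 was 22.1-fold lower (SE 0.496, adjusted p = 5.88e-05, leave-one-out 14.6 to 33.5) and Igfbp3 12.2-fold lower (SE 0.532, adjusted p = 0.000782). Pparg dropped by 4.46-fold (log2 -2.16, SE 0.383, adjusted p = 0.0031), lost without IDMB+EGF+TCDD 2 (0.0832). Adipoq dropped by 5.11-fold (SE 0.506, adjusted p = 0.0105, leave-one-out 3.18 to 8.20), lost without IDMB+EGF+TCDD 1 (0.166). Srebf1 dropped by 1.75-fold (SE 0.14, adjusted p = 0.00268), Acta2 by 3.46-fold (SE 0.195, adjusted p = 4.66e-05). Ccl9 dropped by 24.1-fold (SE 0.43, adjusted p = 9.57e-06) and the Wnt inhibitor Apcdd1 by 9.50-fold (SE 0.314, adjusted p = 1.18e-05). Of the 22 adipocyte genes 10 fell and none rose (15 lower when adjusted over the list alone), with a median of -1.10 (camera adjusted p = 1.84e-10, and adjusted p = 0.0168 with an estimated correlation). Aldh3a1 rose 55.6-fold (SE 0.33, adjusted p = 4.94e-08), Egr1 by log2 3.58 (SE 0.638, adjusted p = 0.0032) and the membrane protein Tmem176a 8.07-fold (SE 0.487, adjusted p = 0.0016, leave-one-out 6.00 to 12.9). Ccn5 rose 7.31-fold (SE 0.26, adjusted p = 7.81e-06), the actin-binding Synpo 7.09-fold (SE 0.273, adjusted p = 1.18e-05). Cyp1b1 rose 2.83-fold (SE 0.185, adjusted p = 0.000165), Nqo1 3.45-fold (SE 0.229, adjusted p = 0.000217) and Cxcl12 3.10-fold (SE 0.209, adjusted p = 0.000217).

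AhR targets had 7 higher and Ugdh lower of 12 with EGF and TCDD in IDMB cultures, the same when adjusted over the list alone (median 1.33, camera adjusted p = 6.11e-05, and adjusted p = 0.0381 with an estimated correlation). Interferon genes had 4 of 19 higher, among them Iigp1 and Irf1 (8 when adjusted over the list alone, median 0.56, camera adjusted p = 5.18e-05, and adjusted p = 0.0421 with an estimated correlation). Bone and cartilage genes had 2 of 9 higher, Bmp4 and Msx1 (4 when adjusted over the list alone, median 0.77, camera adjusted p = 0.000168, and adjusted p = 0.0517 with an estimated correlation). EGF and MAPK responsive genes had 9 higher and Vegfa lower of 30 (12 and 4 when adjusted over the list alone, median 0.45, camera adjusted p = 0.0473, and adjusted p = 0.781 with an estimated correlation). Inflammatory and chemokine genes had 4 higher, among them Cxcl5 and Vcam1, and Ccl9 and Saa3 lower of 19 (7 and 2 when adjusted over the list alone, median 0.42, camera adjusted p = 0.0487, and adjusted p = 0.5 with an estimated correlation). No member of the G2 and mitosis list was called, though the list was higher (median 0.90, camera adjusted p = 4.62e-05, and adjusted p = 0.781 with an estimated correlation). S phase genes were higher with only Pold1 called (median 0.45, camera adjusted p = 0.00252, and adjusted p = 0.781 with an estimated correlation). The comparison had 240 probes higher and 246 lower, or 162 higher and 235 lower after scaling to the same median, with 268 calls without IDMB 2, 179 without IDMB+EGF+TCDD 1 and 120 without IDMB+EGF+TCDD 2. The Gapdh ratio was 2.13 and 2.86 on the IDMB+EGF+TCDD arrays, and 98 probes were called with it as a covariate.

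**Figure D2:**
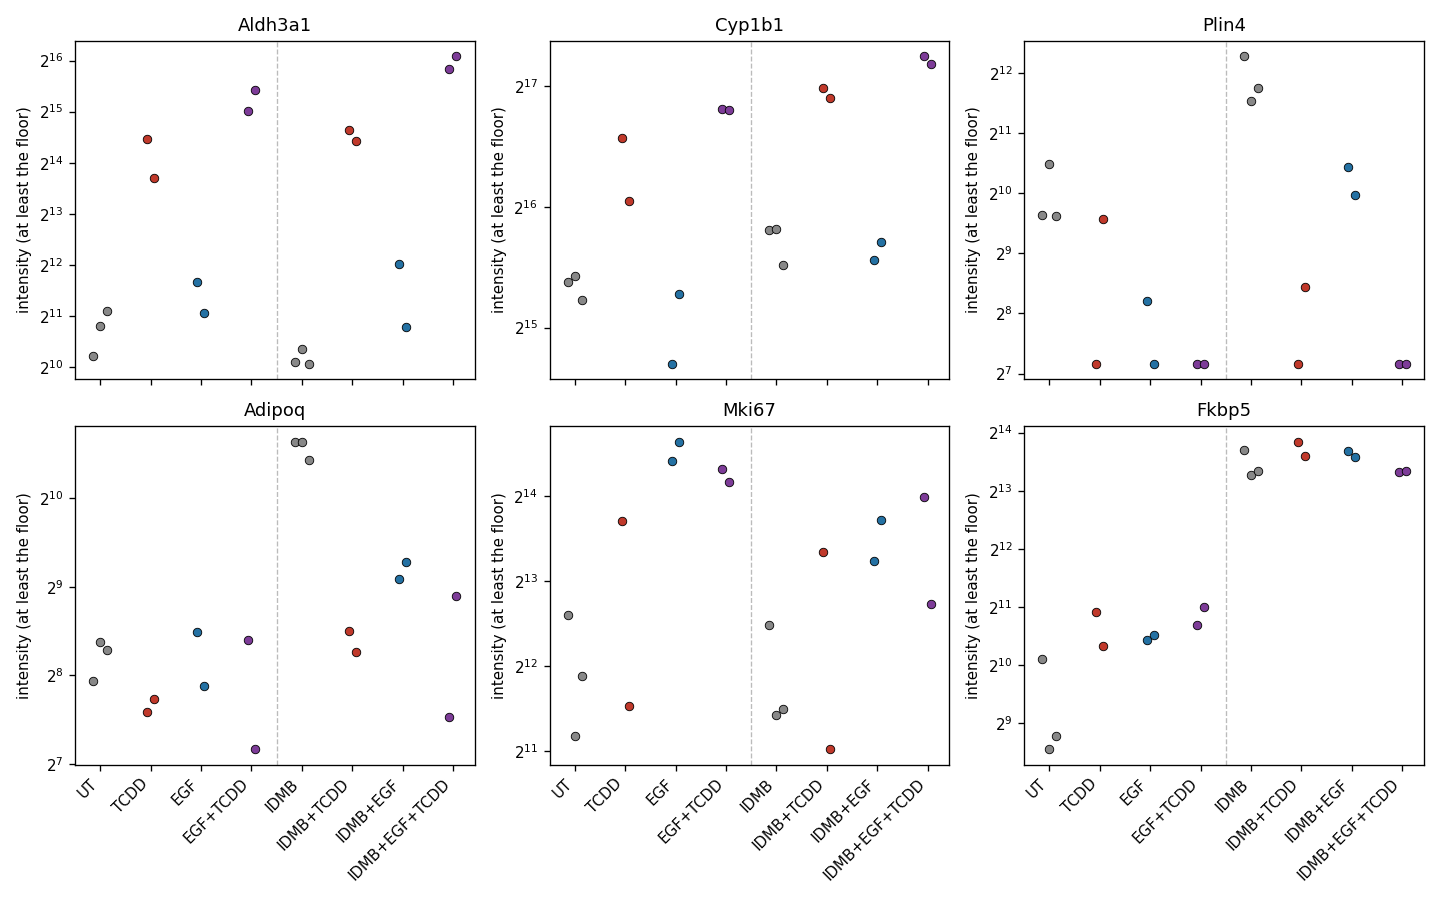
Intensity on each of the 18 arrays, on a log axis, of AhR targets Aldh3a1 and Cyp1b1, fat cell genes Plin4 and Adipoq, the proliferation marker Mki67 and the glucocorticoid-induced Fkbp5. Values under the floor are drawn at the floor.

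In cultures that also had EGF, TCDD raised AhR targets with few other calls (n = 2 against 2). Against EGF alone, Aldh3a1 rose 14.5-fold (log2 3.86, SE 0.362, adjusted p = 7.55e-05), Tiparp 11.5-fold (SE 0.357, adjusted p = 7.81e-05) and Cyp1b1 3.53-fold (SE 0.203, adjusted p = 0.000172). Rflnb, a regulator of actin bundling, dropped by 4.08-fold (SE 0.272, adjusted p = 0.00162). Cyp1a1 rose 20.1-fold (SE 0.658, adjusted p = 0.00494), lost without EGF 2 (0.0704) or EGF+TCDD 1 (0.118). Nqo1 rose by log2 1.62 (SE 0.251, adjusted p = 0.005), lost without EGF 1 (0.101), EGF+TCDD 1 (0.0736) or EGF+TCDD 2 (0.0598). AhR targets had 6 of 12 higher (7 higher and 1 lower when adjusted over the list alone, median 1.27, camera adjusted p = 3.89e-13, and adjusted p = 0.00126 with an estimated correlation). Interferon genes were higher as a list, none called singly and 5 of 19 when adjusted over the list alone (median 0.48, camera adjusted p = 4.02e-08, and adjusted p = 0.0108 with an estimated correlation). Inflammatory and chemokine genes had 2 of 19 higher, Cxcl12 and Saa3 (5 higher and 2 lower when adjusted over the list alone, median 0.50, camera adjusted p = 5.44e-05, and adjusted p = 0.0619 with an estimated correlation). Extracellular matrix genes (median -0.23, camera adjusted p = 0.00717, and adjusted p = 0.287 with an estimated correlation) and G2 and mitosis genes (median -0.31, camera adjusted p = 0.0251, and adjusted p = 0.687 with an estimated correlation) were lower as lists with no member called. In all 17 probes were higher and 3 lower, with 380 under an unadjusted p of 0.05. The count was 11 without EGF 1, 12 without EGF 2, 8 without EGF+TCDD 1 and 12 without EGF+TCDD 2, and 10 with the Gapdh ratio as a covariate.

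Against IDMB+EGF, TCDD raised Aldh3a1 23.8-fold (log2 4.58, SE 0.362, adjusted p = 6.76e-06, leave-one-out 15.5 to 36.6), the cell surface proteoglycan Gpc1 5.22-fold (SE 0.239, adjusted p = 6.65e-05) and Cyp1b1 2.99-fold (SE 0.203, adjusted p = 0.00137), with n = 2 against 2. The lipid droplet gene Plin2 dropped by 2.99-fold (SE 0.242, adjusted p = 0.00676), lost without IDMB+EGF 2 (0.0594) or IDMB+EGF+TCDD 2 (0.103). Cyp1a1 stood at 2.74 and did not pass (adjusted p = 0.11, leave-one-out 1.75 to 3.74), though it did without IDMB+EGF 1 (0.0497). The adipocyte list was lower, with only Plin2 called of 22 (9 lower and 1 higher when adjusted over the list alone, median -0.69, camera adjusted p = 1.36e-07, and adjusted p = 0.0273 with an estimated correlation). AhR targets had 2 of 12 higher (6 when adjusted over the list alone, median 0.74, camera adjusted p = 5.39e-08, and adjusted p = 0.00925 with an estimated correlation). Interferon genes had 1 of 19 higher, Ifi47 (2 when adjusted over the list alone, median 0.47, camera adjusted p = 1.01e-05, and adjusted p = 0.0273 with an estimated correlation). Inflammatory and chemokine genes were higher with no member called (4 higher and 1 lower when adjusted over the list alone, median 0.43, camera adjusted p = 0.00105, and adjusted p = 0.118 with an estimated correlation). Extracellular matrix genes were lower with no member called (1 lower and 1 higher when adjusted over the list alone, median -0.21, camera adjusted p = 0.0143, and adjusted p = 0.314 with an estimated correlation). In all 16 probes were higher and 10 lower, with 505 under an unadjusted p of 0.05. The count was 13 without IDMB+EGF 1 and 6 without IDMB+EGF+TCDD 2, and 5 with the Gapdh ratio as a covariate.

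Averaged over the 4 backgrounds (8 arrays with TCDD against 10 without), TCDD raised AhR targets and interferon genes and lowered adipocyte genes. Aldh3a1 rose 16.5-fold (log2 4.05, SE 0.173, adjusted p = 5.94e-10), Tiparp 5.52-fold (SE 0.171, adjusted p = 1.94e-07). Cyp1a1 rose 5.69-fold (SE 0.315, adjusted p = 0.000188), Nqo1 2.99-fold (SE 0.12, adjusted p = 4.71e-07) and Cyp1b1 2.64-fold (SE 0.097, adjusted p = 1.94e-07). Chil1, at the floor in 1 group, was at least 6.02-fold higher (SE 0.3, adjusted p = 7.65e-05). Ccl9 dropped by 8.22-fold (SE 0.225, adjusted p = 4.34e-07), the chemokine Ccl17 by 3.21-fold (SE 0.293, adjusted p = 0.0026) and Acta2 by 1.70-fold (SE 0.102, adjusted p = 0.000281). Lox was lower by log2 -0.57 (SE 0.104, adjusted p = 0.00375; other probe -0.54, adjusted p = 0.368). Cxcl12 was higher by 0.78 (SE 0.11, adjusted p = 0.000426; other probes 0.42 and 1.21, adjusted p = 0.0865 and 0.000545). Pparg was lower by -0.83 (SE 0.201, adjusted p = 0.0218), lost without TCDD 1 (0.0582), EGF 2 (0.058), EGF+TCDD 2 (0.0652), IDMB+EGF 2 (0.0548) or IDMB+EGF+TCDD 2 (0.0663). The effect had 193 probes higher and 202 lower, or 134 higher and 209 lower after scaling to the same median, with 260 calls without IDMB+EGF+TCDD 2.

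By list, the mean TCDD effect held 7 of 12 AhR targets higher and Ugdh lower (8 and 1 when adjusted over the list alone, camera adjusted p = 1.85e-08, and adjusted p = 0.00624 with an estimated correlation). Relabelling the arrays within each background gave an exact p adjusted to 0.00306 for the AhR score, whose difference was 1.08 and had the same direction in 4 of 4 backgrounds. Adipocyte genes had 7 of 22 lower (12 when adjusted over the list alone, camera adjusted p = 3.72e-10, adjusted p = 0.00624 with an estimated correlation, score difference -0.63, exact adjusted p = 0.00407, 4 of 4 backgrounds). Interferon genes had 7 of 19 higher (9 when adjusted over the list alone, camera adjusted p = 1.16e-08, adjusted p = 0.00624 with an estimated correlation, score difference 0.62, exact adjusted p = 0.00306, 4 of 4 backgrounds). Lower were also extracellular matrix genes, 5 lower and 1 higher of 38 (9 and 1 when adjusted over the list alone, camera adjusted p = 0.000817, adjusted p = 0.117 with an estimated correlation, exact adjusted p = 0.00458). Smooth muscle genes had 3 lower and 1 higher of 15 (8 and 1 when adjusted over the list alone, camera adjusted p = 0.00464, adjusted p = 0.107 with an estimated correlation, exact adjusted p = 0.00856). Inflammatory genes had 5 higher and Ccl9 lower of 19, the same when adjusted over the list alone (camera adjusted p = 0.00704, and adjusted p = 0.166 with an estimated correlation). Bone and cartilage genes had 1 higher, Bmp4, the same when adjusted over the list alone (camera adjusted p = 0.0131, and adjusted p = 0.166 with an estimated correlation). S phase (camera adjusted p = 0.00584, and adjusted p = 0.727 with an estimated correlation) and G2 and mitosis genes (camera adjusted p = 0.0231, and adjusted p = 0.803 with an estimated correlation) were higher as lists with no member called. The score difference of inflammatory genes was -0.51 without other agents and 0.52, 0.10 and 0.47 with EGF, IDMB and both. The exact test called none of these 4 lists (adjusted p of 0.437 for inflammatory, 0.166 for bone and cartilage, 0.278 for S phase and 0.54 for G2 and mitosis genes).

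**Figure D3:**
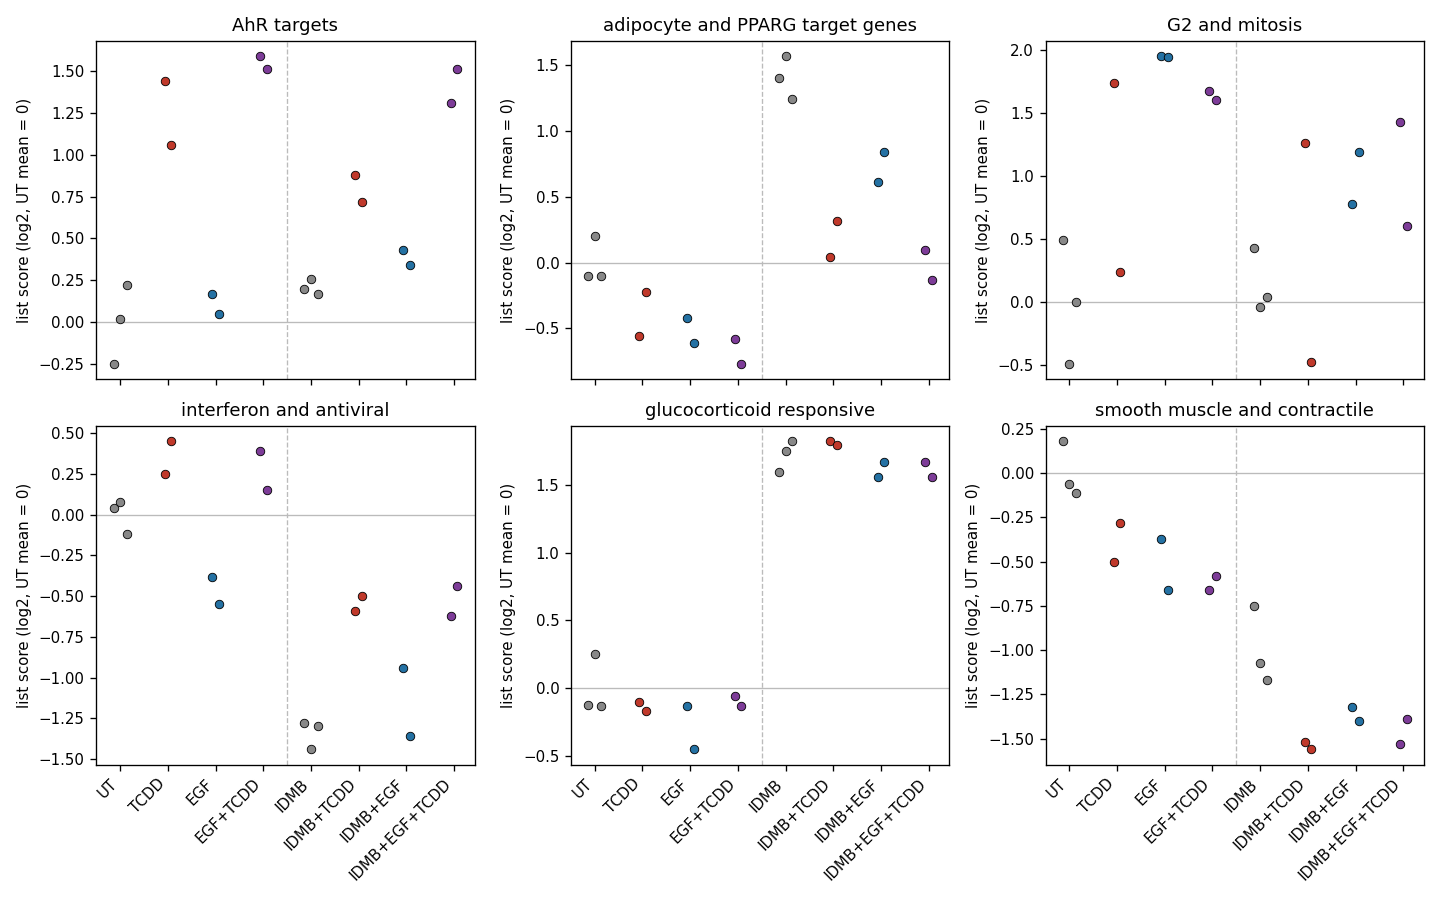
Score of 6 gene lists on each array, as the mean log2 value of the measured genes with the UT mean set to 0. Groups left of the dashed line had no IDMB.

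Averaged over the 4 backgrounds (8 arrays with EGF against 10 without), EGF raised Egr1 and 27 of 33 G2 and mitosis genes. Egr1 rose 5.22-fold (log2 2.38, SE 0.335, adjusted p = 0.000569), Dusp6 4.33-fold (SE 0.274, adjusted p = 0.000484) and Mki67 3.43-fold (SE 0.338, adjusted p = 0.00372). Cdk1 rose 2.29-fold (SE 0.241, adjusted p = 0.00554), Mcm5 2.07-fold (SE 0.199, adjusted p = 0.00368) and Sgk1 2.30-fold (SE 0.22, adjusted p = 0.00309). Saa3, at the floor in 1 group, dropped by at least 5.34-fold (SE 0.211, adjusted p = 2.8e-05). Npy1r dropped by 3.49-fold (SE 0.335, adjusted p = 0.00319), no bound, since arrays with and without EGF were at the floor. Hp dropped by 3.28-fold (SE 0.218, adjusted p = 0.000412), Npr3 by 3.43-fold (SE 0.252, adjusted p = 0.000604; its other probes -1.11 and -0.38, adjusted p = 0.0109 and 0.462). Pparg dropped by 1.84-fold (SE 0.201, adjusted p = 0.011) and the heme oxygenase Hmox1 by 1.58-fold (SE 0.118, adjusted p = 0.00263). Lox was lower by log2 -0.77 (SE 0.104, adjusted p = 0.000548; other probe -0.47, adjusted p = 0.347) and Acta2 by -0.67 (SE 0.102, adjusted p = 0.00104). G2 and mitosis genes had 27 of 33 higher (30 when adjusted over the list alone, median 0.99, camera adjusted p = 1.61e-15, and adjusted p = 0.359 with an estimated correlation). S phase genes had 18 of 30 higher (25 when adjusted over the list alone, median 0.61, camera adjusted p = 2.31e-11, and adjusted p = 0.312 with an estimated correlation). EGF and MAPK responsive genes had 11 higher and Vegfa lower of 30 (12 and 2 when adjusted over the list alone, median 0.33, camera adjusted p = 0.000149, and adjusted p = 0.312 with an estimated correlation). Adipocyte genes had 6 of 22 lower, the same when adjusted over the list alone (median -0.41, camera adjusted p = 0.000244, and adjusted p = 0.312 with an estimated correlation). The exact test on the scores gave adjusted p = 0.0206 for G2 and mitosis (difference 1.01), 0.00856 for S phase (0.59), 0.00458 for EGF and MAPK responsive genes (0.52) and 0.00458 for adipocyte genes (-0.42).

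The mean EGF effect had 504 probes higher and 431 lower, or 386 higher and 426 lower after scaling to the same median. The count was 467 without TCDD 2, 501 without EGF 2, 596 without EGF+TCDD 1, 551 without IDMB+TCDD 2 and 597 without IDMB+EGF+TCDD 1. The Gapdh ratio was 1.43 to 2.86 on the 8 arrays with EGF, 0.854 to 1.09 on the 4 with TCDD but no EGF and 1.19 to 1.73 on the 6 with neither. With the ratio as a covariate 0 probes were called by limma (614 under an unadjusted p of 0.05), while the standard error of the effect grew 2.5-fold.

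Averaged over the 4 backgrounds (9 arrays with IDMB against 9 without), IDMB raised Rgs2 29.0-fold (log2 4.86, SE 0.186, adjusted p = 1.55e-11), Mt1 16.2-fold (SE 0.276, adjusted p = 1.45e-08), and the protease inhibitor Serpina3n 9.98-fold (SE 0.176, adjusted p = 8.19e-10). Cebpb rose 3.52-fold (SE 0.096, adjusted p = 8.19e-10) and Cebpd 2.40-fold (SE 0.095, adjusted p = 4.45e-08). Fabp4, the fat cell fatty acid binding protein, rose 2.52-fold (SE 0.193, adjusted p = 5.52e-05), Pparg 1.80-fold (SE 0.201, adjusted p = 0.00376) and Acadm, which starts the breakdown of medium-chain fatty acids, 2.13-fold (SE 0.103, adjusted p = 6.36e-07). Acta2 dropped by 10.4-fold (SE 0.102, adjusted p = 1.22e-12), Ccl2 by 9.99-fold (SE 0.272, adjusted p = 1.17e-07), the cyclin Ccnd1 by 8.12-fold (SE 0.188, adjusted p = 4.9e-09). Plaur dropped by 4.05-fold (SE 0.269, adjusted p = 2.52e-05) and Isg15 by 5.74-fold (SE 0.242, adjusted p = 7.29e-07). Ifit3, at the floor in 1 group, dropped by at least 7.31-fold (SE 0.279, adjusted p = 8.4e-07). Sqle of cholesterol synthesis dropped by 3.87-fold (SE 0.21, adjusted p = 2.55e-06), the ER chaperone Hspa5 by 1.65-fold (SE 0.126, adjusted p = 0.000314). Mcm5 dropped by 2.19-fold (SE 0.199, adjusted p = 0.000349), the ribonucleotide reductase Rrm2 by 2.26-fold (SE 0.201, adjusted p = 0.000269) and the preadipocyte marker Dlk1 by 1.83-fold (SE 0.132, adjusted p = 8.61e-05). The effect had 1104 probes higher and 1328 lower, from 2078 to 2457 calls when any 1 array was left out. Scaling to the same median turned the balance, to 1263 higher and 1035 lower. The actin ratio was 1.23 to 1.93 without IDMB and 1.80 to 3.80 with it, and with it as a covariate 448 probes were called, with standard errors 2.24-fold larger.

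Lists that rose in the mean IDMB effect were glucocorticoid responsive genes (21 higher and 2 lower of 27, camera adjusted p = 1.11e-13, and adjusted p = 0.0053 with an estimated correlation) and adipocyte genes (13 and 1 of 22, camera adjusted p = 4.16e-06, and adjusted p = 0.0292 with an estimated correlation). So did adipogenic transcription factors (9 and 1 of 15, camera adjusted p = 8.65e-05, and adjusted p = 0.0122 with an estimated correlation) and cAMP responsive genes (2 and 1 of 8, camera adjusted p = 0.0442, and adjusted p = 0.175 with an estimated correlation). When adjusted over the list alone each of these 4 lists had the same counts. S phase genes had 24 of 30 lower (27 when adjusted over the list alone, median -0.73, camera adjusted p = 7.91e-08, and adjusted p = 0.258 with an estimated correlation). Of 33 G2 and mitosis genes 7 fell (6 when adjusted over the list alone, camera adjusted p = 0.00725, and adjusted p = 0.649 with an estimated correlation). Cholesterol synthesis genes had 9 of 12 lower, the same when adjusted over the list alone (median -1.17, camera adjusted p = 0.000268, and adjusted p = 0.179 with an estimated correlation). ER stress genes had 13 lower and 1 higher of 25 (13 and 2 when adjusted over the list alone, camera adjusted p = 0.00725, and adjusted p = 0.23 with an estimated correlation). Interferon genes had 12 of 19 lower (13 lower and 1 higher when adjusted over the list alone, camera adjusted p = 5.18e-05, and adjusted p = 0.0292 with an estimated correlation). Smooth muscle genes had 9 lower and 1 higher of 15 (10 and 1 when adjusted over the list alone, camera adjusted p = 4.61e-05, and adjusted p = 0.0262 with an estimated correlation). Matrix genes had 16 lower and 8 higher of 38 (17 and 9 when adjusted over the list alone, camera adjusted p = 0.0344, and adjusted p = 0.258 with an estimated correlation). In the exact test, the score differences of glucocorticoid (1.82), adipocyte (0.97) and interferon genes (-0.93) each had an adjusted p of 0.00102. G2 and mitosis genes did not pass it (-0.51, adjusted p = 0.142, 3 of 4 backgrounds in the same direction).

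When TCDD was present, the adipocyte genes kept a part of the IDMB response, while the median glucocorticoid gene kept it whole. The 12 adipocyte genes called with IDMB kept a median of 41.6% of their log2 effect with TCDD (quartiles 34.7 and 66.3), 83.2% with EGF (67.9 and 131) and 47.4% with both (17.5 and 68.6). The 19 glucocorticoid genes kept 110% (quartiles 77.8 and 127), 99.5% (73.8 and 162) and 101% (61.9 and 137), and the 9 adipogenic transcription factors 54.7% (32.1 and 131), 83.3% (69.7 and 151) and 45.5% (33.1 and 129). Over all 22 adipocyte genes the median IDMB effect was 1.82 with no other agent, 0.62 with TCDD, 1.59 with EGF and 0.43 with both, and 12, 6, 11 and 3 of them were called. The difference of the IDMB response with and without TCDD was lower for the adipocyte list by camera (adjusted p = 0.00136, and adjusted p = 0.191 with an estimated correlation). For the 475 probes higher with IDMB the medians were 1.06, 0.75, 0.85 and 0.56 in the same order, and for the 529 lower -0.97, -0.68, -0.62 and -0.50. These probes were picked in IDMB against UT, so a smaller median elsewhere arises in part from that choice.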

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

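Interactions, which test whether an effect differed between backgrounds, had few calls by limma. The TCDD effect differed with IDMB for 8 of 7134 probes (2 higher and 6 lower, 571 under an unadjusted p of 0.05). The chemokine receptor Ackr3 was higher by log2 1.56 with IDMB (SE 0.245, adjusted p = 0.00814) and the semaphorin receptor Nrp1 by 1.08 (SE 0.165, adjusted p = 0.00789), although the other probe of Nrp1 was not called (1.27, adjusted p = 0.132). The AhR regulator Tiparp was lower by -2.47 (SE 0.342, adjusted p = 0.00714) and Mtss2 by -1.79 (SE 0.277, adjusted p = 0.00789). The lipid droplet coat gene Plin2 was lower by -1.57 (SE 0.231, adjusted p = 0.0075) and the triglyceride lipase Pnpla2 by -1.39 (SE 0.199, adjusted p = 0.00714). The count was 14 without IDMB 3 and 14 without IDMB+EGF+TCDD 1.

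In that interaction the adipocyte list was lower with Plin2 and Pnpla2 called (7 lower and 1 higher when adjusted over the list alone, median -0.46, camera adjusted p = 1.22e-05, and adjusted p = 0.129 with an estimated correlation). AhR targets were lower with only Tiparp called (2 lower and 1 higher when adjusted over the list alone, median -0.37, camera adjusted p = 0.0408, and adjusted p = 0.353 with an estimated correlation). Camera also called S phase (adjusted p = 0.0302, and adjusted p = 0.944 with an estimated correlation), inflammatory (0.0408, and adjusted p = 0.464 with an estimated correlation) and bone and cartilage genes (0.0113, and adjusted p = 0.315 with an estimated correlation).

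The EGF effect differed with IDMB for 9 probes (4 higher and 5 lower, or 3 higher and 1 lower after quantile normalization, 865 under an unadjusted p of 0.05). Between 0 and 21 were called when 1 array was left out, and no gene held in all of these fits. S phase genes (median -0.44, camera adjusted p = 0.00129, and adjusted p = 0.656 with an estimated correlation) and G2 and mitosis genes (median -0.57, camera adjusted p = 0.00129, and adjusted p = 0.693 with an estimated correlation) were lower as lists.

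Without IDMB, the effects of EGF and TCDD together differed from their sum for 26 probes (19 higher and 7 lower, 1139 under an unadjusted p of 0.05, and 1 to 113 when 1 array was left out). The acute phase gene Saa3 differed by at least log2 5.80 (SE 0.597, adjusted p = 0.000284), with the EGF arrays at the floor. Inflammatory and chemokine genes had 3 higher, Cxcl12, Lcn2 and Saa3, and Cx3cl1 lower of 19 (7 and 1 when adjusted over the list alone, median 0.74, camera adjusted p = 0.00053, and adjusted p = 0.352 with an estimated correlation). G2 and mitosis genes (median -1.32, camera adjusted p = 2.58e-07, and adjusted p = 0.663 with an estimated correlation) and S phase genes (median -0.81, camera adjusted p = 5.78e-05, and adjusted p = 0.663 with an estimated correlation) were lower, and fatty acid oxidation genes higher (median 0.28, camera adjusted p = 0.0215, and adjusted p = 0.663 with an estimated correlation). With IDMB the same interaction had 70 probes (42 higher and 28 lower, 981 under an unadjusted p of 0.05, and 1 to 79 when 1 array was left out), and bone and cartilage genes were lower (median -0.91, camera adjusted p = 0.00407, and adjusted p = 0.342 with an estimated correlation). With the Gapdh ratio as a covariate each of these last 2 counts was 1.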

How the results depend on the processing

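Only the alternatives named here were fitted, 1 change at a time (the filter on the mean also changed its percentile). The cause of a moved count was not tested. All counts are limma calls, and the Gapdh, actin and 1 probe per gene settings were chosen after seeing the data. Leaving out 1 array moved most counts of groups with 2 arrays. Of the 166 named pairs of gene and comparison, 34 lost their call with the Gapdh covariate, 10 at adjusted p under 0.01, 9 with no filter, 1 with no floor and a pseudocount of 16, and 0 with quantile normalization, median scaling or a robust fit. With only the groups compared, 7 of the 115 pairs that have such a fit lost it, and with the actin covariate 11 of 48. The robust fit and the pseudocount moved no count by over 1.5 times. With any of the 18 arrays left out, 2934 values of named genes were unchanged, 49 lost and 5 gained a call. Genes were named mainly for holding there, so this was partly chosen. Opposite signs were seen for another probe of Angptl4 in IDMB vs UT (-0.857). Cebpa in IDMB+TCDD vs IDMB, never called, changed sign with the replicate block (0.238), without IDMB 3 (0.143) or IDMB+TCDD 1 (0.055).

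The replicate numbers were not taken to pair the arrays, since the labels name nothing shared by a number and not every same-numbered pair correlated over 0.1. Residuals of arrays with the same number correlated at a median of 0.047 (57 pairs, from -0.103 to 0.438, highest for UT 1 and IDMB 1), 14 pairs were over 0.1, and 13 of 18 arrays correlated best with an array of their own number, a hint of sharing from the data alone. The score of G2 and mitosis genes was higher on number 1 than on number 2 in 7 of 8 groups. A test added after this was seen kept the numbers, and EGF against no EGF within numbers 1 and 2 gave an exact p of 0.0156 (mean difference 1.00, 7 of 8 differences higher). With the replicate number as a block the calls were 1123 for IDMB vs UT, 816 for TCDD vs UT, 632 for EGF vs UT, 585 for EGF+TCDD vs UT, 647 for IDMB+TCDD vs IDMB, 441 for IDMB+EGF vs IDMB, 622 for IDMB+EGF+TCDD vs IDMB, 38 for IDMB+EGF+TCDD vs IDMB+EGF and 24 for EGF+TCDD vs EGF. They were 575, 1059 and 2541 for the mean effects of TCDD, EGF and IDMB, 14 for TCDD by IDMB, 15 for EGF by IDMB, and 178 and 162 for EGF by TCDD without and with IDMB. Each of these counts was higher than in the main fit, which had no block.

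When 1 array was left out the calls ran from 788 to 1050 for IDMB vs UT, 114 to 641 for TCDD vs UT, 14 to 508 for EGF vs UT, 46 to 428 for EGF+TCDD vs UT, 151 to 528 for IDMB+TCDD vs IDMB, 30 to 305 for IDMB+EGF vs IDMB and 120 to 520 for IDMB+EGF+TCDD vs IDMB. They ran from 6 to 33 for IDMB+EGF+TCDD vs IDMB+EGF, 8 to 24 for EGF+TCDD vs EGF, 260 to 463 for the TCDD mean effect, 467 to 1018 for the EGF mean effect, 8 to 14 for TCDD by IDMB, 0 to 21 for EGF by IDMB, and 1 to 113 and 1 to 79 for EGF by TCDD without and with IDMB.

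With only the groups compared in the fit, calls were 627 for IDMB vs UT, 112 for TCDD vs UT, 232 for EGF vs UT, 140 for IDMB+TCDD vs IDMB, 72 for IDMB+EGF vs IDMB, 175 for IDMB+EGF+TCDD vs IDMB, 11 for IDMB+EGF+TCDD vs IDMB+EGF, and 3 and 2 for EGF by TCDD without and with IDMB. At adjusted p under 0.01 they were 583 for IDMB vs UT, 128 for TCDD vs UT, 83 for EGF vs UT, 84 for EGF+TCDD vs UT, 185 for IDMB+TCDD vs IDMB, 79 for IDMB+EGF vs IDMB, 155 for IDMB+EGF+TCDD vs IDMB, 8 for IDMB+EGF+TCDD vs IDMB+EGF, 160, 285 and 1605 for the mean effects of TCDD, EGF and IDMB, 0 for EGF by IDMB, and 1 and 9 for EGF by TCDD without and with IDMB. At a fold of at least 1.5 the mean effects had 203, 410 and 1186. With no filter there were 338 for TCDD vs UT, 184 for EGF vs UT, 165 for EGF+TCDD vs UT, 309 for IDMB+EGF+TCDD vs IDMB, 12 for EGF+TCDD vs EGF, 15 for TCDD by IDMB and 27 for EGF by TCDD with IDMB.

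With array weights calls were 1148 for TCDD vs UT, 926 for EGF vs UT, 821 for EGF+TCDD vs UT, 93 for IDMB+EGF vs IDMB, 36 for EGF+TCDD vs EGF, 16 for EGF by IDMB and 346 for EGF by TCDD without IDMB. With no trend they were 244 for EGF+TCDD vs UT, 0 for EGF by IDMB, and 15 and 33 for EGF by TCDD without and with IDMB. A floor at the 40th percentile gave 16 for TCDD by IDMB and 52 for EGF by TCDD without IDMB, a filter on the mean at the 60th percentile gave 16 for EGF by IDMB, and quantile normalization 4 for EGF by IDMB. Median scaling gave 2 for EGF by IDMB, and 13 and 38 for EGF by TCDD without and with IDMB. With 1 probe per gene there were 352 for TCDD vs UT, 17 for IDMB+EGF+TCDD vs IDMB+EGF, 15 for EGF by IDMB and 12 for EGF by TCDD without IDMB.

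With the Gapdh covariate calls were 36 for TCDD vs UT, 189 for EGF vs UT, 10 for EGF+TCDD vs UT, 267 for IDMB+TCDD vs IDMB, 98 for IDMB+EGF+TCDD vs IDMB, 5 for IDMB+EGF+TCDD vs IDMB+EGF, 10 for EGF+TCDD vs EGF, 0 for the EGF mean effect, 0 for EGF by IDMB, and 1 and 1 for EGF by TCDD without and with IDMB. Standard errors grew 1.36-fold for TCDD vs UT, 1.54-fold for EGF+TCDD vs UT and 1.52-fold for IDMB+EGF+TCDD vs IDMB. With the actin covariate calls were 482 for IDMB vs UT and 448 for the IDMB mean effect. An estimated correlation gave 26 list calls, against 94.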

Other observations

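Some gene groups moved that the accounts above do not cover. With TCDD already present, EGF had 114 probes higher and 136 lower (EGF+TCDD against TCDD, n = 2 against 2), and fatty acid oxidation and mitochondria genes had 3 of 31 higher, Cox6c, Uqcrc2 and Cox4i1 of the respiratory chain (7 when adjusted over the list alone, median 0.20, camera adjusted p = 0.0312, and adjusted p = 0.758 with an estimated correlation). With IDMB and TCDD present, EGF had 11 probes higher and 9 lower, and AhR targets were higher as a list with no member called (3 when adjusted over the list alone, median 0.39, camera adjusted p = 0.0105, and adjusted p = 0.469 with an estimated correlation). Against TCDD, IDMB+TCDD had 6 higher, among them Acadm and Pdha1, and Cs, citrate synthase, lower of 31 fatty acid oxidation genes, the same when adjusted over the list alone (median 0.23, camera adjusted p = 0.0255, and adjusted p = 0.405 with an estimated correlation). With EGF, exact tests of the scores also gave cAMP responsive genes (0.40, adjusted p = 0.00458) and insulin and IGF axis genes (-0.23, adjusted p = 0.00458). They gave AhR targets (0.30, adjusted p = 0.0192) and smooth muscle genes (-0.26, adjusted p = 0.0192, 3 of 4 backgrounds in the same direction) too, and camera called none of these 4 lists for the mean EGF effect. With IDMB, exact tests gave 6 lists that camera did not call for the mean effect. They were EGF and MAPK responsive (-0.48, adjusted p = 0.0017), insulin and IGF axis (0.29, 0.00102), bone and cartilage (-0.78, 0.00102), adipogenesis inhibitors (-0.21, 0.00364), fatty acid synthesis (0.20, 0.00475) and fatty acid oxidation genes (0.09, 0.0325, 3 of 4 backgrounds).

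Several comparisons moved the same probes. TCDD vs UT and EGF vs UT, which share the UT arrays, had 43 probes higher in both (9.94 if independent) and 61 lower in both (6.99), with 1 opposite. Their fold changes correlated at 0.53 where simulated data with shared controls gave 0.40, and covaried at 0.186 against 0.0511. IDMB+TCDD vs IDMB and IDMB+EGF vs IDMB, which share the IDMB arrays, had 62 higher in both (4.19 if independent) and 74 lower in both (4.73), with a correlation of 0.64 against 0.39 simulated and a covariance of 0.212 against 0.0507. The 3 control arrays cannot be split in parts of 2, so a part of either excess may come from them. TCDD vs UT had 178 calls without UT 2. Pairs with no shared array had a simulated correlation of 0. TCDD without and with IDMB gave 0.44 (54 higher in both against 8.46 if independent, 57 lower against 9.57, 1 opposite). Likewise EGF gave 0.41 (22 higher against 4.92, 21 lower against 3.46, 2 opposite). EGF+TCDD gave 0.45 (45 higher against 7.10, 42 lower against 6.00, 3 opposite). The 0 and the independent counts hold for unrelated arrays, and same-numbered UT and IDMB arrays may share deviations.

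Of the tests below, those that relabel or split the arrays for the counts and the one that predicts the mitosis score from the Gapdh ratio were written before their results were seen, and all others were chosen or reworded after. A test on fewer arrays, with 178 calls for TCDD vs UT without UT 2 against 20 for EGF+TCDD vs EGF, was dropped after its value was seen. So was a test for a compressed range with quantile normalization (adipocyte list median -0.90 before and -0.89 after), because the value exceeded by 0.1% of probes was no lower on the IDMB+TCDD arrays (166843 and 177594) than on the IDMB arrays (144564 to 164879). Splits and relabellings asked whether chance could give the counts. For IDMB vs UT the 10 splits are too few to tell (1004 calls, highest other 15). Chance could be excluded for the mean effects of TCDD (395 calls, highest other 131), EGF (935, highest other 76) and IDMB (2432, highest other 1395), where the real labels alone reached their count, 1 of 100 relabellings each.

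TCDD vs UT had 548 calls while EGF+TCDD vs EGF had 20, and an odd group might account for it. Simulated data with these numbers of arrays gave 147 and 127 calls, so fewer arrays alone gave no such drop there. RNA quality as a possible explanation was not settled. With the Gapdh ratio as a covariate 91.6% of the mean change of the called probes was left (95% interval 73.8% to 109%). These probes were picked by their calls in the same arrays, and their mean change does not test the drop in calls. With the covariate 36 probes were called for TCDD vs UT and 10 for EGF+TCDD vs EGF. Standard errors grew 1.36-fold and 1.13-fold. A chance deviation of the arrays remains open, because 83.6% of the called probes moved the same way in IDMB+TCDD vs IDMB, where the highest of the other splits gave 78.3. A difference of the UT and IDMB arrays from all others also remains open, because 70.8% moved the same way in IDMB+EGF vs IDMB, which had no TCDD, against 44% in EGF+TCDD vs EGF and 51.6% in IDMB+EGF+TCDD vs IDMB+EGF.

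G2 and mitosis genes were higher with EGF by a score of 1.01, and differences between cultures unrelated to EGF might give this. Relabelling the arrays within backgrounds gave an exact p of 0.0075, which excludes chance labels at the level set. RNA quality could not be told apart, because the slope on the Gapdh ratio within groups predicted 0.0337 with a 95% interval from -1.55 to 1.61. The score also differed between the TCDD arrays (1.74 and 0.24) and between the IDMB+TCDD arrays (1.26 and -0.47), which may point to a variable state of growth of the cultures that was not tested.

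The adipocyte list was lower when TCDD was added to IDMB, and a weaker response to the whole mix or RNA quality might give this. Glucocorticoid genes called with IDMB kept a median of 110% of their effect with TCDD, so the response was weaker in part at most. With the Gapdh covariate 104% of the mean change was left (95% interval 69.5% to 138%). The groups' ratios did not overlap, so RNA quality stays open. So does an action of TCDD on the PPARG branch, which a repeat with rosiglitazone alone could test.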
